A study of Homo sapiens with 2 samples.

How the data were processed

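RNA was taken from HT-29 cells, a human colon adenocarcinoma epithelial line, per the labels' protocols. One library came from cells carrying a scramble control and 1 from cells in which GPR126 was knocked down by RNA interference. Each group therefore held 1 library, and no label describes a second culture, hairpin or sequencing run. The aligner, counting tool, annotation and genome build are not given in the sources used here.

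The data were a single table of 2007 genes, identified by Entrez number and symbol, in which the authors compared the libraries. Per the file headers and values, the authors deposited a whole-number count per gene and library. The authors also deposited a column headed TPM. For every count above 0 it equalled the count divided by 1 library total and multiplied by 1e6, within 0.005 (100% of values). It is therefore an RPM value with no gene length in it, and a count of 0 was entered by the authors as 0.01. The totals that these values imply were 5753320 reads for the scramble library and 6010192 reads for the knockdown library. The listed genes took 15.8% of the scramble total and 11.5% of the knockdown total. The authors' deposited log2 ratio (knockdown over scramble), p-value and FDR complete the table, together with gene start and end positions that carry no chromosome and no build and were not used here.

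The deposited table holds selected genes. The smallest absolute log2 ratio in it is 1 and the largest FDR is 0.001. A gene that is not listed may have been unchanged, changed by less than 2-fold, too weakly expressed to pass, or not supplied, and these cases could not be separated. For the 1301 lower genes with a p-value above 1e-200, every deposited p-value lay within 1% of a 2-sided Audic-Claverie test computed from the counts and totals. For the higher genes 279 of 600 did; the form of the upper tail was chosen among several after the values were seen, and the authors' test is not given in the sources used here. That test knows counting error only, so the deposited p-values compare these libraries, not the conditions, and none is used as evidence here.

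From the counts, a log2 ratio of knockdown over scramble was computed per gene with 0.5 reads added to each count and each library scaled to its total. A fold was computed from the counts without a pseudocount, with an exact Clopper-Pearson 95% interval conditional on the gene's summed count. These intervals cover counting error only; they contain nothing of the variation between cultures. Where 1 library had a count of 0, the fold is given as a lower bound against 3 counts in that library. A floor of 1 RPM in the higher library removed no gene. No differential expression test was run, because with 1 library per group there is no replicate error. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

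Before the data were examined, 33 gene lists were fixed for signalling, proliferation, differentiation, stress, metabolism, contaminating cell types and RNA interference. Members were matched by Entrez number through current symbols (2004 of 2007 identifiers matched GRCh38.p14 RefSeq names) or by the symbol in the table; 3 symbols had become dates and 1 was blank. For each list with at least 5 listed members, the median log2 ratio was set against 10000 random lists of listed genes, of the same size and matched on mean expression in 20 bins. The resulting percentiles describe these libraries; genes are not replicates. Because most listed genes were lower, a random list usually has a negative median.

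Genes are named in the text by a rule also fixed beforehand. It takes GPR126, GLI2 and HDAC2, the 4 listed members of each list with the largest ratios, the 12 highest and 12 lowest ratios among genes with at least 100 reads in the higher library, and the 5 most abundant genes of each library. Clone names, LOC numbers, open reading frame names and other provisional identifiers were left out of the highest and lowest ratios. As the table holds only called genes, the rules ran within it. Where the text names a gene outside this rule, the gene was chosen after its values were seen. Some genes that the rule takes are not reported here.

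Libraries were simulated with the real totals and the 2007 genes' mean levels, with counting (Poisson) error alone and no selection of genes by ratio. On these, the interval held the true fold for 96% of genes. It excluded equality for 88% of genes changed by a log2 of 1 or -1, for 100% of those changed by 2 or -2, and for 4.1% of unchanged genes. The median estimate at a true log2 of 2 was 2.00. The interval assumes the same error, so the simulation checks the calculation only. It does not cover genes selected at 2-fold, as the listed genes were. Alternatives covered the pseudocount, the floor, the scaling, the size of the ratio, the unit used, the authors' threshold and the matching of the random lists. Gene ontology terms in the deposited table were examined only after the data had been seen.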

Results

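Gene expression was profiled by RNA sequencing in HT-29 colon cancer cells to ask which transcripts differ when GPR126 is knocked down. GPR126, now named ADGRG6, is an adhesion G protein-coupled receptor known to bind type IV collagen and laminin-211 and to be needed for Schwann cell myelination. The scramble library held 5753320 reads and the knockdown library 6010192. With 1 library per group, every difference below is between these 2 libraries and has no replicate check. The intervals are 95% counting intervals. Only genes that the authors listed as differing were available, so values for unlisted genes are not reported.

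The target itself was lower in the library labelled as the knockdown. GPR126 (Entrez 57211) had 68 reads in the scramble library, or 11.8 reads per 1e6 (RPM), and 2 reads in the knockdown library, or 0.33 RPM. That is a 35.5-fold lower level with a counting interval of 9.46 to 299, wide because of the 2 remaining reads. The log2 ratio was -4.84 with 0.5 reads added, and -5.16 in the authors' deposited table. Of the 28 adhesion receptors in the fixed list, 2 others were listed. GPR110 (ADGRF1) was 4.72-fold higher (3.59 to 6.31), and BAI2 (ADGRB2), with 38 and 11 reads, was 3.61-fold lower (1.81 to 7.83).

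Most listed genes were lower in the knockdown library. The authors' deposited table lists 668 genes as higher and 1339 as lower. From the counts, 660 were at least 2-fold higher and 1332 at least 2-fold lower. This excess disappeared among larger differences: 166 genes were at least 4-fold higher and 164 at least 4-fold lower, and 50 were at least 8-fold higher against 15 lower. The whole counting interval lay beyond 2-fold for 329 higher and 664 lower genes. The lower genes had a median of 227 scramble and 94 knockdown reads, and the higher genes a median of 42 scramble and 122.5 knockdown reads. The split depended on scaling to the library total: when the upper quartile, a trimmed mean or the median of the listed genes was used, 668 genes were 2-fold higher and 292, 164 or 112 were 2-fold lower. Those scalings draw on selected genes only, and genes that are not listed but would pass 2-fold higher after them are missing from the 668.

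**Figure D1:**
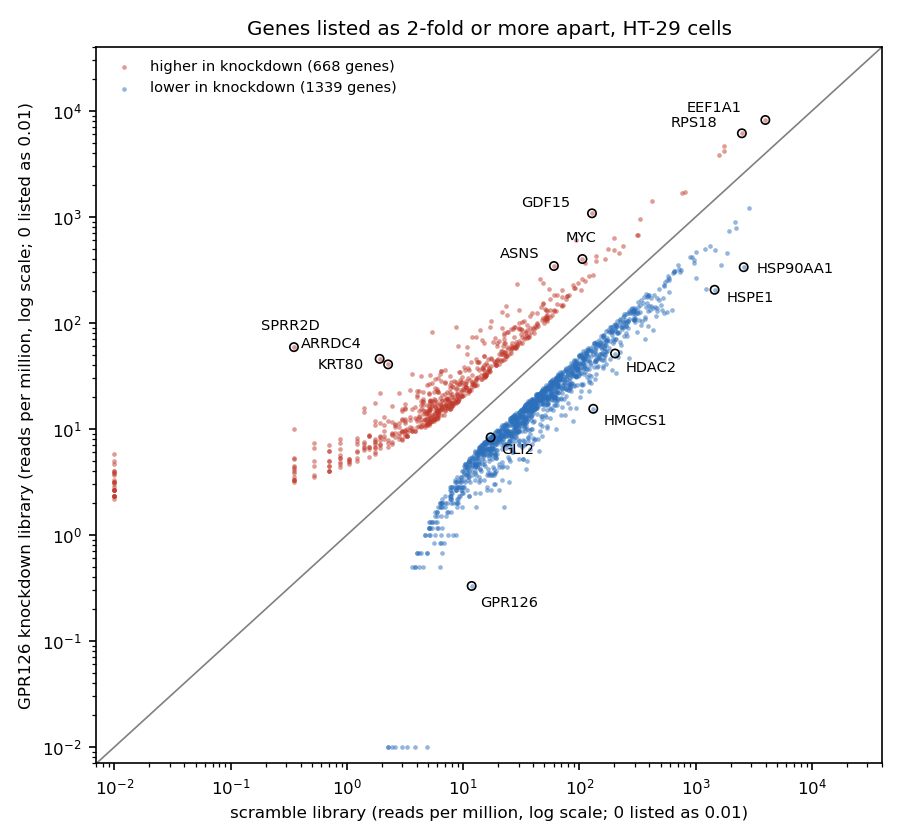
RPM in the scramble library (x axis) and the GPR126 knockdown library (y axis), both on log scales, for the 2007 listed genes; each point is 1 gene, red where higher and blue where lower in the knockdown, and a count of 0 is drawn at 0.01. GPR126 lies at 11.8 and 0.33 RPM, and the empty band along the diagonal reflects the 2-fold limit of the listed genes.

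Among genes with at least 100 reads in the higher library, 12 were named for the lowest ratios in the knockdown. HSP90AA1, the inducible cytosolic HSP90, had 14873 scramble and 2015 knockdown reads and was 7.71-fold lower (7.36 to 8.08). HSPE1, the mitochondrial co-chaperonin, was 7.08-fold lower (6.67 to 7.52), and PPP5C, a phosphatase that binds HSP90, was 7.28-fold lower (5.15 to 10.6). The 12 lowest ratios also held the carbohydrate kinase SHPK (12.2-fold, 6.57 to 25.0), the sterol pathway enzyme HMGCS1 (8.49-fold, 6.84 to 10.6), FAM111B (8.32-fold, 5.47 to 13.2), DSCR6 (7.86-fold, 4.85 to 13.4), the protein kinase A regulatory subunit PRKAR2B (7.57-fold, 4.47 to 13.7) and the replication factor GINS1 (7.37-fold, 5.75 to 9.57). The others were COBRA1 of the negative elongation factor complex, the mitochondrial transporter ABCB10 and DCAF15, between 6.34-fold and 7.03-fold lower.

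The highest ratios belonged to genes with few scramble reads. SPRR2D, a cornified envelope protein gene, had 2 scramble and 355 knockdown reads, a 169.9-fold difference with a counting interval of 46.7 to 1408. The alpha-arrestin ARRDC4 was 23.9-fold higher (13.2 to 48.5), the keratin KRT80 18.0-fold (10.3 to 34.2), the uridine phosphorylase UPP1 15.3-fold (10.6 to 22.7), RBCK1 10.5-fold (7.83 to 14.3) and the stress transcription factor ATF3 10.1-fold (5.31 to 21.8). The secreted factor GDF15 had 737 scramble and 6489 knockdown reads and was 8.43-fold higher (7.81 to 9.11). SCG2, TP53INP1, LYRM1 and RGS16 were between 6.70-fold and 7.90-fold higher. SPRR2D belongs to a cluster of near-identical genes, and how shared reads were assigned is not given in the sources used here.

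Genes of DNA replication were lower together. Of 28 fixed S-phase genes, 21 were listed and all 21 were lower, with a median log2 ratio of -1.61. No random list of 10000 matched on expression had a median as low, and 0.36% had as many lower members. Of the MCM helicase subunits, MCM4 was 5.65-fold lower (4.18 to 7.78), MCM6 5.25-fold (4.36 to 6.35) and MCM5 5.11-fold (4.01 to 6.57). GINS2 was 5.22-fold lower (4.18 to 6.58). CCNE2 alone changed sign when the median of the listed ratios was set to 0. Of 28 mitosis genes 12 were listed and all 12 were lower, among them BIRC5 (3.49-fold, 3.01 to 4.06), KIF11 (3.40-fold, 2.59 to 4.51), DLGAP5 (3.15-fold, 2.32 to 4.33) and NDC80 (2.92-fold, 2.23 to 3.86). The median of the mitosis list, -1.36, lay at percentile 6.66 of random lists, and 2.51% of these had as many lower members; BUB1 changed sign under the median scaling.

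Cholesterol synthesis genes were also lower. Of 24 fixed genes 17 were listed, 16 of them lower and 1, the reductase TM7SF2, 2.10-fold higher (1.67 to 2.65). The median log2 ratio was -1.75, and no random list had a median as low, although 3.49% had as many lower members. HMGCS1 had the lowest ratio, followed by MVD (5.25-fold lower, 4.72 to 5.84), EBP (4.64-fold, 3.91 to 5.53) and CYP51A1 (4.53-fold, 3.98 to 5.16). The listed sterol regulators SREBF2 and INSIG1 were lower too, INSIG1 4.07-fold (3.41 to 4.87) and SREBF2 2.24-fold (1.73 to 2.92); both, like TM7SF2, were singled out after their values were seen.

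All 9 listed members of the 20 p53 targets were higher, with a median log2 ratio of 1.89 that no random list reached. GDF15 and TP53INP1 (7.20-fold, 4.73 to 11.4) led them, followed by ZMAT3, with 4 and 24 reads (5.74-fold, 1.97 to 22.8), and PLK3 (4.08-fold, 3.35 to 5.0002). Of 22 amino acid response genes, targets of the transcription factor ATF4, 7 were listed and 6 were higher. The list median of 2.33 was not reached by any random list. ASNS, asparagine synthetase, had 347 scramble and 2067 knockdown reads (5.70-fold higher, 5.09 to 6.41), DDIT4 was 5.20-fold higher (3.32 to 8.51) and VEGFA 5.03-fold higher (4.19 to 6.08). The exception was the amino acid transporter SLC7A5, 2.33-fold lower (2.12 to 2.56) and named after its value was seen.

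In the endoplasmic reticulum stress list 5 of 20 genes were listed and 4 were higher, with a median log2 ratio of 1.19 at percentile 96.9. DDIT3, which encodes CHOP, was 6.01-fold higher (4.86 to 7.50), PPP1R15A 5.51-fold (3.87 to 8.04) and ATF4 itself 2.28-fold (2.14 to 2.44). SDF2L1 was 2.22-fold lower (1.85 to 2.68) and reached 0.01 under the median scaling. Of 24 apoptosis regulators 5 were listed, 4 of them higher, with a median of 1.49 at percentile 97.4. The BH3-only gene PMAIP1 had 541 scramble and 3657 knockdown reads (6.47-fold higher, 5.91 to 7.10), BIK was 3.01-fold higher (2.16 to 4.28) and BIRC3 2.87-fold (1.60 to 5.42).

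**Figure D2:**
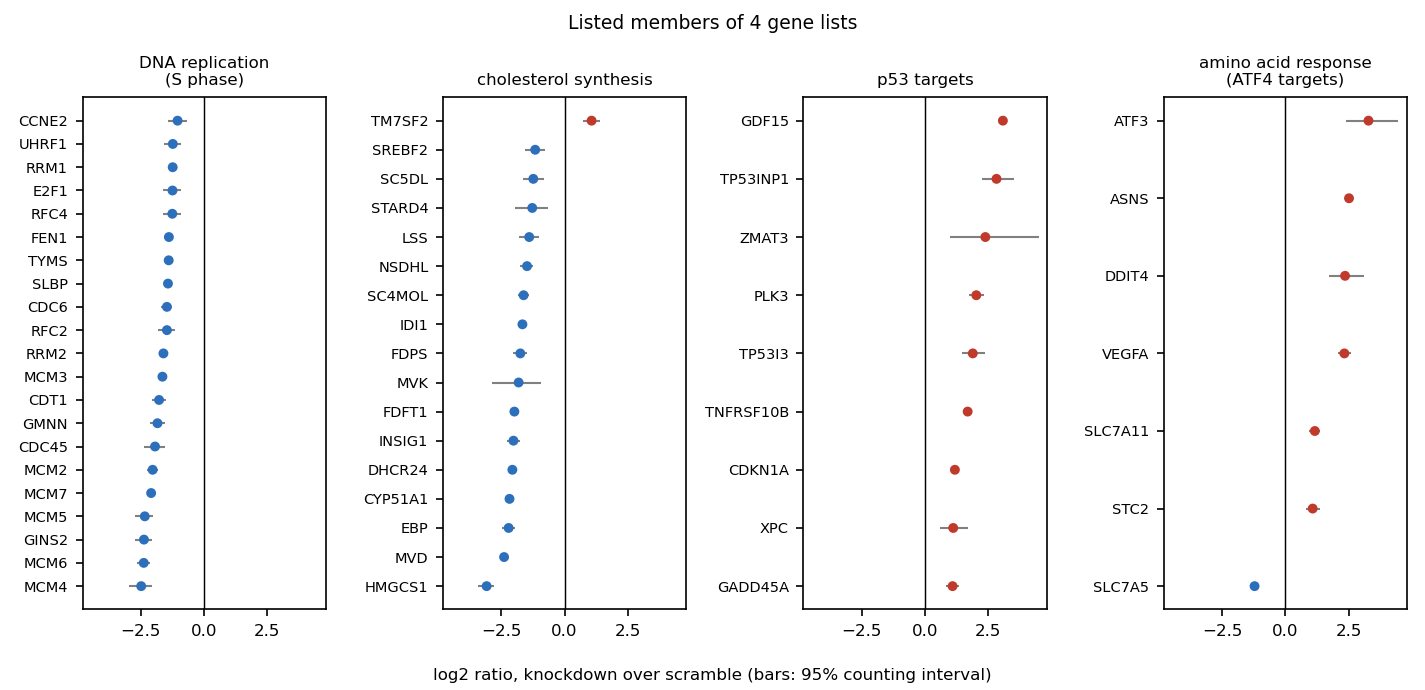
Log2 ratio of knockdown over scramble (x axis) for each listed member of 4 fixed gene lists; points are genes, red where higher and blue where lower, and grey bars are 95% counting intervals. All 21 replication genes lie below 0 and all 9 p53 targets above it.

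HDAC2 and GLI2, which were named beforehand, were both lower. HDAC2, a class I deacetylase, had 1164 scramble and 309 knockdown reads and was 3.94-fold lower (3.47 to 4.48). GLI2, a Hedgehog transcription factor, had 99 and 50 reads and was 2.07-fold lower (1.46 to 2.97), but its log2 ratio became 0.12 when the median of the listed ratios was set to 0. In each list 1 further gene was listed, and it was higher: the Hedgehog acyltransferase HHAT (4.31-fold, 2.14 to 9.59, with 10 and 45 reads) and HDAC4 (3.003-fold, 2.18 to 4.20). The remaining 16 Hedgehog genes and 9 deacetylases were not listed.

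Of 23 cAMP and immediate early genes, 5 were listed and all 5 were higher, and the other 18 were not listed. The 5 had a median log2 ratio of 1.86 at percentile 99.4. They were ATF3, which is also in the ATF4 target list, JUN (5.48-fold, 4.18 to 7.30), PDE4D, AREG and JUNB. The epidermal growth factor receptor ligand AREG had 2408 scramble and 8519 knockdown reads and was 3.39-fold higher (3.24 to 3.54). Of 17 MAPK feedback genes, 12 were not listed and the 5 listed were higher, with a median of 1.41 at percentile 95.1. DUSP5 (5.87-fold, 4.85 to 7.15) and EPHA4 (5.38-fold, 2.51 to 13.2) led them. The basement membrane list of 21 genes holds the receptor's known ligands. All 5 of its listed genes were higher, with a median of 2.22 at percentile 99.8. They included LAMB3 (6.22-fold, 5.18 to 7.52), HSPG2 (5.33-fold, 3.55 to 8.29), COL4A5 (4.91-fold, 2.27 to 12.1) and LAMA3. The other 16, among them LAMA2, a chain of laminin-211, were not listed. Of 16 integrins only ITGAE was listed, 2.17-fold lower (1.80 to 2.61) but at a log2 ratio of 0.05 under the median scaling.

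Among Wnt targets MYC was 3.77-fold higher (3.45 to 4.13), with 610 and 2405 reads, whereas AXIN2 (3.15-fold, 2.32 to 4.33), TCF7 (2.74-fold, 2.15 to 3.51) and DKK1 (2.70-fold, 2.40 to 3.05) were lower; the other 16 were not listed. Of 14 Notch genes HES1 was listed, 2.0006-fold higher (1.55 to 2.61). Of 28 hypoxia and glycolysis genes 6 were listed, and these were divided. NDRG1 (4.88-fold, 4.29 to 5.57), VEGFA and ANKRD37 were higher, and PGAM1, with 7099 and 1256 reads (5.90-fold, 5.56 to 6.27), ALDOA and LDHA were lower, LDHA changing sign under the median scaling. The median of the 6, 0.15, lay at percentile 94.1.

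All 11 listed genes of the 39 nuclear oxidative phosphorylation genes were lower, led by COX5A (5.02-fold, 4.57 to 5.54) and COX8A (3.01-fold, 2.77 to 3.27). Their median of -1.18 was at percentile 55.0, and 5.48% of random lists had as many lower members; 4 of the 11 changed sign under the median scaling. Of 44 cytosolic ribosomal protein genes in the fixed list 4 were listed, 3 of them higher and 1 lower. RPS18 was 2.46-fold higher (2.41 to 2.51) and RPL26 2.68-fold higher (2.62 to 2.74). RPS15 was 2.05-fold higher (1.51 to 2.79) with 65 and 139 reads. The elongation factor EEF1A1, the most abundant listed gene of both libraries, had 22831 scramble and 49265 knockdown reads and was 2.07-fold higher (2.03 to 2.10), S100A6 was 2.39-fold higher (2.34 to 2.45) and the chaperone HSPA8 2.80-fold lower (2.71 to 2.89). Many of these genes have processed pseudogenes, so their counts depend on an assignment of reads that is not given in the sources used here.

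**Figure D3:**
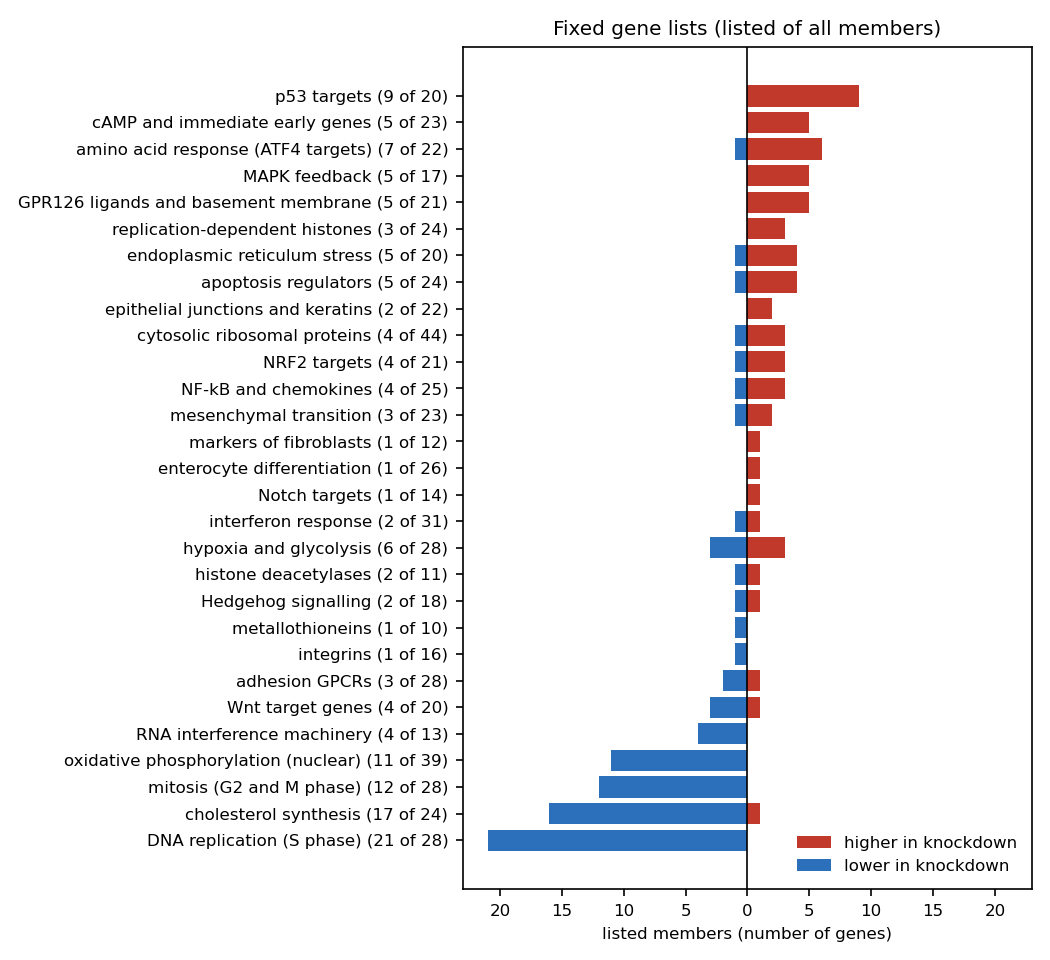
Number of listed members (x axis) that were lower (blue, to the left) or higher (red, to the right) in the knockdown library for each fixed gene list with a listed member; brackets give listed of all members. The replication list, with 21 lower, and the p53 list, with 9 higher, are at the ends.

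Lists for differentiation and for other cell types held few listed genes. None of 21 goblet and secretory genes, 15 mitochondrially encoded genes, 14 leukocyte markers and 11 endothelial markers was listed. Of 26 enterocyte genes CEACAM1 was listed (6.80-fold higher, 3.49 to 14.8), and of 12 fibroblast markers COL1A1 (2.62-fold higher, 2.03 to 3.41). TJP3 and ESRP1 were higher among 22 epithelial genes, at 5.15-fold (2.39 to 12.7) and 2.85-fold (2.55 to 3.20). Of 23 mesenchymal genes 3 were listed; SNAI1 was higher (2.01-fold, 1.43 to 2.86) and SPARC was 4.85-fold lower (2.69 to 9.36). In the interferon list of 31, IRF7 was higher (10.4-fold, 5.06 to 24.9, with 8 and 87 reads) and IFI6 lower (2.25-fold, 1.86 to 2.74). The chemokine genes IL8 (CXCL8) and CXCL3 were 6.13-fold (2.37 to 20.1) and 4.79-fold (1.96 to 14.1) higher from 5 and 6 reads, and BIRC3 was higher while NFKB1 was 2.34-fold lower (1.83 to 3.001). Among NRF2 targets SLC7A11, ME1 and GSR were between 2.04-fold and 2.24-fold higher and PGD was 2.69-fold lower (2.38 to 3.04). The metallothionein MT1F was 4.05-fold lower (2.31 to 7.52). The histone genes HIST1H1C, HIST1H2BD and HIST2H2BE were between 3.998-fold and 5.74-fold higher. Of 13 RNA interference genes TARBP2 was 2.71-fold lower (1.88 to 3.97), and EIF2C2 (AGO2), DICER1 and DGCR8 were between 2.01-fold and 2.23-fold lower, these 3 changing sign under the median scaling.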

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

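No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. The direction of GPR126, of 12 list medians and of all but 6 of the other 109 named genes was the same under each pseudocount and scaling tried. Little could reverse, since the table is limited to 2-fold and many named genes were taken for large ratios. Only the median scaling removed a shift clearly beyond a log2 of 1. By construction it puts as many listed genes above 0 as below, so the 6 do not show how many listed genes turned. Changing the pseudocount to 0.05 or 5 reads left every named gene inside its counting interval, and unmatched random lists left all 12 list percentiles inside or outside the middle 95% as before. A floor of 5 RPM left 608 higher and 1311 lower genes. Removing the floor, a 1.5-fold limit, the authors' RPM values in place of counts and the planned threshold on the authors' calls (FDR of 0.001 with a 2-fold ratio) say nothing about stability, since every listed gene passed the floor and the table is already limited to 2-fold and that FDR. The scalings computed from the listed genes removed a log2 shift of -1.16 (median), -1.001 (trimmed mean) or -0.71 (upper quartile), which follows from computing them on listed genes alone, most of which were lower. All 3 moved every ratio upward, so no higher gene or list could reverse under them. They took the genes 2-fold lower from 1332 to 112, 164 and 292. In the same order they gave list medians of -0.45, -0.61 and -0.90 for replication, -0.20, -0.36 and -0.66 for mitosis, -0.59, -0.75 and -1.04 for cholesterol synthesis, -0.017, -0.18 and -0.47 for oxidative phosphorylation, and 3.38, 3.23 and 2.93 for basement membrane. For p53 targets the median and trimmed mean gave 3.05 and 2.89, for ATF4 targets 3.49 and 3.33, and for MAPK feedback the median gave 2.57. With the median scaling, 6 named genes reversed: SDF2L1 to 0.0098, EIF2C2 to 0.016, DICER1 to 0.032, ITGAE to 0.046, GLI2 to 0.12 and DGCR8 to 0.16. A 4-fold limit left 166 higher and 164 lower genes. Chosen after seeing the data, an 8-fold limit left 50 and 15, a counting interval wholly beyond 2-fold 329 and 664, and an FDR of 1e-10 among the authors' deposited calls left 251 higher and 845 lower. The FDR split cannot be compared between directions. Deposited values of lower genes followed the counting test, whereas those of higher genes often did not. MYC, higher with 610 and 2405 reads, had a deposited FDR of 6.88e-12, and SPRR2D, with 2 and 355 reads, only 0.000389. HDAC2, lower with 1164 and 309 reads, had 2.23e-123. Depth limits the genes with few reads: 25 listed genes had no read in the scramble library and 8 none in the knockdown library, and their ratios depend on the pseudocount.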

Other observations

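The tests of GC content, length and scaling on the split of directions, and of the interferon list, were chosen after the result was seen, as were the gene groups of the first 3 paragraphs. The table carries gene ontology terms, and 135 terms with 12 to 400 listed genes were set against random lists matched on expression. All 37 listed members of the spliceosomal complex were lower, against 9.52 higher members in an average random list, and 60 of 61 RNA splicing genes were lower. The splicing genes included SRSF3 (4.66-fold lower, counting interval 4.32 to 5.04), SRSF7 (4.14-fold, 3.50 to 4.91) and RNPS1 (4.17-fold, 3.62 to 4.82). Of 183 mitochondrial genes 157 were lower. None of 10000 random lists had as many lower members for any of these 3 terms, nor for DNA replication (44 of 45 lower), DNA repair (37 of 41), cell division (59 of 61), mitosis (48 of 51) and nucleoplasm (94 of 109). The other terms at 0.1% or less were cell cycle (98 of 114) and mRNA processing (34 of 36). The mitosis term holds more listed genes than the fixed mitosis list, for which 2.51% of random lists had as many lower members. For the fixed oxidative phosphorylation list 5.48% did, and its median lay at percentile 55.0. These term counts rest on direction alone. The median log2 ratio was -1.21 for mitochondrial genes, -1.26 for the spliceosomal complex and -1.62 for DNA replication. It was -1.16 over all listed genes, which include the higher ones. The lower genes alone had a median fold of 2.57. The mitochondrial and spliceosomal medians were smaller falls than that, and the DNA replication median was a larger one. Under the median scaling, lower members above -1.16 would count as higher. All 13 listed genes of the proteasome complex term were lower, among them PSMC3 (4.001-fold, 3.40 to 4.72), but 2.69% of random lists matched that. PSMA2, a proteasome gene outside that term, was 5.70-fold lower (5.01 to 6.49). The chaperonin subunits CCT7 (5.25-fold, 4.54 to 6.10) and CCT3 (3.85-fold, 3.64 to 4.07) were lower as well, and 27 of 32 protein folding genes were lower, which 7.66% of random lists matched. The cell cycle regulators E2F2, SKP2 and CDK2 were 5.54-fold, 5.53-fold and 2.97-fold lower.

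Terms with an excess of higher genes were of several kinds. Of 13 epidermis development genes 11 were higher (4.33 in an average random list), among them the laminin chains LAMB3 and LAMA3, SPRR2D, the epithelial transcription factor ELF3 (6.10-fold, 4.82 to 7.81) and CTGF (3.51-fold, 1.96 to 6.69). Of 14 genes annotated to the hypoxia response 12 were higher (4.86 in an average random list). Of 101 extracellular region genes 58 were higher, against 38.9. As many higher members came up in 0.01% of random lists for epidermis and in none for the hypoxia and extracellular region terms. The other terms at 0.1% or less were extracellular space (24 of 38 higher), regulation of DNA-dependent transcription (50 of 86), multicellular organismal development (39 of 71) and plasma membrane (83 of 188). Under the median scaling of the listed genes, which removed a log2 shift of -1.16, each lower gene of these terms with a ratio above that value would count as higher. Among the 135 terms, 10 passed 0.1% as lower and 7 as higher, where 0.14 per direction would pass if genes varied independently. Overlapping terms share genes, and genes of a term can vary together between any 2 cultures. With 1 library per group these counts therefore do not exclude a chance difference between cultures.

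Genes with no read in 1 library gave lower bounds only. IL20RB, with 35 knockdown reads, was at least 11.2-fold higher; KRT86, with 30, at least 9.57-fold; S100P, with 22, at least 7.02-fold. KRT86 has near-identical hair keratin neighbours. MYB, a transcription factor of colon progenitors, had 28 scramble reads and none in the knockdown, at least 9.75-fold lower. Among snoRNA host genes GAS5 (2.18-fold, 2.10 to 2.25), SNHG12 (2.35-fold), SNHG5 (2.19-fold) and SNHG8 (3.66-fold) were higher and SNHG7 was 2.17-fold lower, a direction that the median scaling turned.

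The higher levels of p53 and ATF4 targets are of interest because HT-29 is known to carry a mutant p53; 15 of the 16 listed genes of the 2 lists were higher. The 2 lists were pooled after their direction was seen, so a share of random lists is no measure of chance here. It shows only how many higher genes GC content alone would give. In 10000 random lists matched on transcript GC content the mean was 5.13 higher genes and the most was 12. That argues against GC content as the whole cause. An interferon response to the hairpin stays open, since only 2 of 31 interferon genes were listed and 1 of them was higher. An off-target effect of the hairpin may equally account for it, as 1 hairpin library cannot separate that from loss of GPR126, and variation between single cultures is open in the same way. That loss of GPR126 itself raises these genes is an untested hypothesis.

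At 2-fold, more listed genes were lower than higher. Scaled to the library total, the share of lower genes was 72.4%, 67.8% and 62.6% in the lowest, middle and highest GC group of 3 equal groups of genes. Each interval lay above 50% (58.8% to 66.4% in the last), but these intervals treat genes as independent. At that scaling a GC trend is present but is not the whole cause. Across 3 equal groups by transcript length the lowest share was 66.0%, which at the same scaling argues against length. The median scaling evens the split by construction, so both readings hold for the library total only. Scaling stays open: a common log2 shift of 0.37, or 1.29-fold, would leave 655 listed genes 2-fold lower and 668 higher, and the unlisted genes that would place the centre were not analysed here. The 668 leaves out unlisted genes that such a shift would carry past 2-fold, so it is not a full count, and a smaller shift could even the split.

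Ribosomal protein genes, which usually vary together, were listed in both directions: 6 of 86 higher and 4 lower. The lower genes included RPS25, RPL22 and RPL28, which turned higher under the median scaling of the listed genes, and the higher ones included RPS15, RPS18, RPL26 and RPL9. Reads shared with pseudogenes were considered as a source. The listed genes had a median of 4.5 annotated pseudogenes (GENCODE 29) against 8.5 for the others, at percentile 20.5 of random sets. This comparison set listed against other genes, so it cannot tell why the directions differed. That neither excludes nor favours read sharing, and RPL28, with 0 such pseudogenes, was 2.12-fold lower. A biological explanation through GPR126 is untested.

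The FDR and p-value columns of the authors' deposited table imply, if the FDR is a Benjamini-Hochberg adjustment, that at least 9702 genes were tested.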
